A study of Mus musculus with 81 samples.

How the data were processed

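Polyadenylated RNA was sequenced from the brain hemisphere and the retina of female C57BL/6J mice, either of the APP/PS1 line or wild type (WT). Per the labels' protocols, left hemispheres and left retinas were taken, total RNA was extracted with Trizol, and mRNA was captured with poly-dT oligonucleotides on magnetic beads. The labels name the brain source as the whole brain while the protocol names the left hemisphere. A letter R stands in the file names of 9 retina libraries (4 APP/PS1 and 1 WT at 2 months, 4 APP/PS1 at 6 months), although the protocol speaks of left retinas. The letter thus nearly coincides with genotype in retina, and the retina comparisons cannot fully tell them apart. The library preparation kit, the read length and the strand setting of the counting are not given in the sources used here.

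The deposited values were read counts per Ensembl gene, 1 file per library, which the authors had not normalized. Trimmomatic, Bowtie and HTSeq are named in the submitters' processing notes, without versions, with the genome build mm10. The file names instead carry the name of the STAR aligner, so the aligner was left open. The annotation release used for counting is not given in the sources used here. Each file held 50600 genes, of which 50376 were given a symbol and a position from a mouse annotation of the build GRCm38. The 5 summary lines of HTSeq were kept out of library sizes and tests. Reads in no annotated feature equalled 14.6% of the gene counts in brain and 23.4% in retina, ambiguous reads 4.11% and 3.91%, and reads with several alignments 12.2% and 12.6%. Because reads with several alignments were not counted, genes with near-identical copies are uncertain. The strand setting being unknown, reads of overlapping antisense genes cannot be told apart.

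Groups were taken from the labels as tissue, age and genotype. Brain held 60 libraries in 8 groups, with 5, 9, 13 and 7 WT and 5, 5, 11 and 5 APP/PS1 libraries at 2, 4, 5 and 6 months. Retina held 21 libraries in 4 groups, with 5 and 6 WT and 5 and 5 APP/PS1 libraries at 2 and 6 months. The labels do not state that the replicates of a group were separate animals, so p-values measure the spread between these libraries. Animal numbers in the file names tied 20 brain libraries to 20 retina libraries. Total gene counts ran from 27.3 to 91.6 M reads per library (median 52.2 M). No 2 libraries of a group were one library deposited again: the chi-square per degree of freedom between libraries of a group was at least 3.22.

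The library numbers in the file names fell into 4 runs, called pools here: A and B (earlier numbers, brain), C (earlier numbers, retina) and D (later numbers, both tissues). They were inferred from the names and are not labelled. In brain, pools A, B and D held 3, 0 and 2 APP/PS1 and 5, 0 and 0 WT libraries at 2 months, 1, 0 and 4 against 7, 0 and 2 at 4 months, 5, 6 and 0 against 3, 10 and 0 at 5 months, and 0, 1 and 4 against 0, 7 and 0 at 6 months. In retina, pool D held 2 of 5 APP/PS1 libraries at 2 months, 4 of 5 at 6 months and no WT library. The 6-month retinas of pool D were also those with the letter R.

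The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, robust fit) on the deposited counts, with TMM normalization, the tool's default filter on low counts, and Benjamini-Hochberg adjustment within a comparison at 0.05. All 8 brain groups entered one fit with a term for 3 pools (21409 genes tested), and all 4 retina groups one fit with a term for 2 pools (19934 genes). The difference between tissues was tested in the 20 animals with both, with the animal as a block and a tissue by library series term (22365 genes). The biological coefficient of variation was 0.0852 in brain, 0.313 in retina and 0.220 in the joint fit. Levels are CPM after TMM normalization unless a sentence says CPM of total counts. Fold changes are log2 values with the standard error (SE) of the fit. App, Prnp and Psen1 were also compared within each tissue and age by a two-sided permutation test of log2 CPM, exact except at 5 months, where 100000 resamples were drawn.

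Before the data were examined, 36 gene lists were fixed, together with the groups, the comparisons, the designs, the alternatives except those stated otherwise, and the rule for naming genes. The lists covered the transgenes and promoter, homeostatic and plaque-associated microglia, complement, interferon response, antigen presentation, reactive astrocytes, astrocyte identity, myelin, oligodendrocyte precursors, glutamatergic, GABAergic and striatal neurons, thalamus and cerebellum, immediate early genes, endothelium and mural cells, choroid plexus, meninges, blood, leukocytes, oxidative phosphorylation, the mitochondrial genome, ribosome, heat shock and endoplasmic reticulum (ER) stress, the circadian clock, cholesterol synthesis, amyloid processing, rods, cones, bipolar, amacrine and ganglion cells, Muller glia, pigment epithelium, lens, and a list of cornea, iris, ciliary body and muscle. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Members passing after adjustment over the list alone are given beside those passing over all genes. Reactive glia and pigment cell lists share genes with other lists, and brain and retina both express many members of the neuronal lists.

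The genes named are, for each comparison, the 8 with the largest rise and the 8 with the largest fall among genes that passed at a mean of at least 1 CPM and carry a symbol other than a predicted gene or clone name, up to 4 passing members per list, the 2 members with the smallest p of a list described, App, Psen1 and Prnp, and, where no gene passed, the 3 with the smallest p. Not every gene the rule allows is named, and other genes are said to have been chosen after their values were seen.

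Alternatives were DESeq2 1.42.0, median-of-ratios size factors, no filter on low counts, no pool term, 2 library series in place of 3 pools, the earlier pools alone, only the groups compared, the replicate number of the labels as a block, the letter L or R of the retinas, and each library of the smaller groups left out in turn. Fits without particular libraries were added after seeing the data. The steps were tested on simulated counts with changed genes planted in the real designs. For brain at 6 months (21409 genes), 53.7%, 77.6% and 93.9% of the genes changed 1.25, 1.5 and 2 fold were recovered, with 4 false calls. For retina at 6 months (19934 genes) 0%, 0% and 13.6% were recovered, and for the tissue difference at 6 months (22365 genes) 0%, 1.49% and 9.09%, each with 0 false calls. These 2 simulations took the spread of fits that hold retina 2-month APP/PS1 libraries 1 to 3, which were rich in muscle transcripts. Tables and permutation tests were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.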

Results

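Brains and retinas of female APP/PS1 mice were profiled at several ages beside those of WT mice, to stage the disease model by gene expression, as the title of the series states. APP/PS1 mice carry transgenes for mutant forms of the amyloid precursor protein and presenilin, and are used as a model of amyloid deposition. RNA was sequenced from 60 brain hemispheres at 2, 4, 5 and 6 months and from 21 retinas at 2 and 6 months. Total gene counts ran from 27.3 to 91.6 M reads per library, and from 39.8 to 58.9 M among the retinas.

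The genes of the transgenes were read first, as a check of the genotype labels. App (chromosome 16, 84949685 to 85173766, GRCm38), which encodes the amyloid precursor protein, was at 3506 ± 53.8 CPM of total counts in APP/PS1 brain at 2 months and 1749 ± 33.0 in WT (SD, n = 5 and 5), a ratio of 2.01 (exact permutation p = 0.00794, adjusted p = 0.00840). The ratio was 2.04 at 4 months, 2.08 at 5 months and 1.99 at 6 months, with every APP/PS1 library above every WT library of its age. In retina the ratio was higher, at 4.56 at 2 months (1462 ± 371 against 311 ± 18.0, n = 5 and 5) and 5.48 at 6 months (1775 ± 140 against 324 ± 15.4, n = 5 and 6). Prnp (chromosome 2, 131909928 to 131938429), the prion protein gene whose promoter drives the transgenes of the line as generally described, was 2.94, 3.11, 2.91 and 2.89 times the WT level in brain at 2, 4, 5 and 6 months and 2.82 and 4.00 times in retina. Psen1 (chromosome 12, 83688152 to 83735199), the presenilin gene, moved far less, with ratios of 1.05 to 1.13 in brain and 1.14 to 1.15 in retina. Its ranges in the 2 genotypes overlapped in brain at 4, 5 and 6 months. All 18 tests of these 3 genes passed after adjustment, the highest adjusted p being 0.0202 for Psen1 in brain at 6 months. These permutation tests leave out the library pools, which nearly coincide with genotype in brain and retina at 6 months and overlap with it in part at 2 months. They also overlap in brain at 4 months, where pool D held 4 of 5 APP/PS1 and 2 of 9 WT libraries. In the edgeR fit with the pool term, App and Prnp passed in each tissue and age and Psen1 in brain at 5 months and retina at 2 months, its adjusted p being 0.59, 0.20 and 1.0 in brain at 2, 4 and 6 months and 0.43 in retina at 6 months. The Psen1 call in retina at 2 months was lost without APP/PS1 1 to 3 (0.13, adjusted p = 0.564). In that fit the genotypes of this age lay in different pools, so the loss cannot decide on the call. Psen1 then stood at 60.8 ± 0.654 against 57.5 ± 1.04 CPM (SD, n = 2 and 5). Counts were made on mouse genes, so reads of a transgene with human sequence appear here only where they aligned to the mouse gene.

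**Figure D1:**
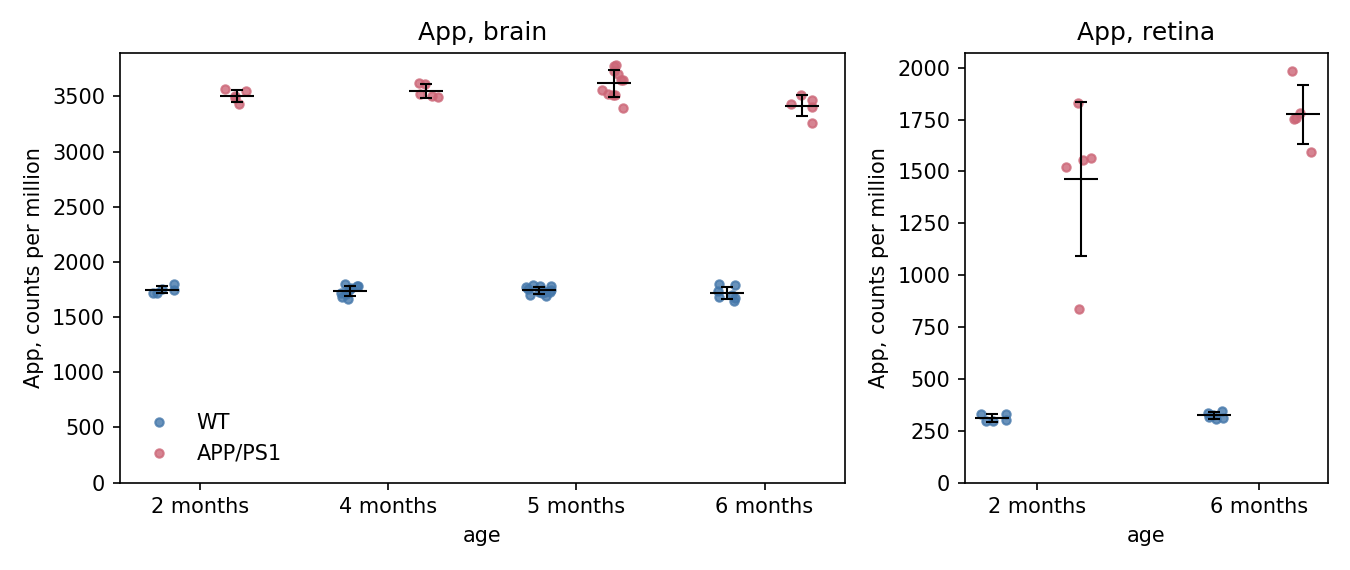
App in CPM of total counts (linear axis from 0) for brain at 4 ages and retina at 2 ages. Each point is a library, blue for WT and red for APP/PS1, the black dash is the mean and the bars are 1 SD; the APP/PS1 libraries of each age lie above all WT libraries, from 3260 CPM upwards in brain at 6 months and from 837 in retina at 2 months.

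At 2 months in brain, chaperones of the endoplasmic reticulum (ER) were lower and genes of cholesterol synthesis higher in APP/PS1 than in WT. Hspa5, the main ER chaperone, fell by 0.72 on the log2 scale (SE 0.16, adjusted p = 0.0405), from 488 ± 71.2 to 304 ± 44.5 CPM (SD, n = 5 and 5). In mean CPM of total counts, Hspa5 in WT brain was at 483 at 2 months and 361, 327 and 337 at 4, 5 and 6 months. In APP/PS1 brain it was at 302, 264, 321 and 296 at these ages, so 2-month WT stood above every other group. Manf, a secreted protein of ER stress, changed by -0.64 (SE 0.13, adjusted p = 0.0124), Pdia4, a disulfide isomerase, by -0.70 (adjusted p = 0.0237), Hsp90b1 by -0.38 (adjusted p = 0.0223) and Herpud1 by -0.32 (adjusted p = 0.0238). In the heat shock and ER stress list, 5 of 20 genes fell and none rose, 17 fell when adjusted over the list alone, the median was -0.41, and the list passed (adjusted p = 6.36e-24, and 0.0336 with an estimated correlation). Dnajc3 (-0.39) and Pdia3 (-0.39), ER proteins outside that list, also fell. Of 18 cholesterol synthesis genes 3 rose, 17 when adjusted over the list alone, with a median of 0.30 (adjusted p = 2.23e-24, and 0.0244 with an estimated correlation). They were Srebf2 (0.19), the regulator of the pathway, Nsdhl (0.29) and Dhcr24 (0.27, from 101 ± 4.79 to 118 ± 10.1 CPM), and the sterol transporter Stard4 (0.45) and Acat2 (0.33) rose as well.

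Other lists passed at 2 months with the preset correlation only. Of the clock genes, Hlf changed by -0.22 (adjusted p = 0.0101) and Nr1d2 by -0.31 (adjusted p = 0.0115), and in the circadian list 8 of 18 genes fell and 1 rose when adjusted over the list alone (adjusted p = 0.000101, and 0.0945 with an estimated correlation). Endothelial and mural genes (median 0.08, adjusted p = 0.00264, and 0.296 with an estimated correlation) and the mitochondrial genome (median -0.09, adjusted p = 0.0182, and 0.891) followed. Abca8a, a lipid transporter, fell (-0.39), as did Cys1 (-0.61), while Zfp941 rose (0.26). Ifit3 (-0.54, adjusted p = 0.25) of the interferon list and C5ar1 (-0.92, adjusted p = 0.34) of the complement list did not pass. App rose by 1.01 (SE 0.03, adjusted p = 1.35e-39), Prnp stood at 1707 ± 102 against 581 ± 10.2 CPM, and Psen1 was at 0.07 (adjusted p = 0.59). Lamr1-ps1 (chromosome 2, 131904086 to 131904959), a pseudogene beside Prnp, was at 5.74 ± 0.55 CPM in APP/PS1 and 0 in all 5 WT libraries, and as a processed copy its reads are uncertain. Arpp21 (chromosome 9, 112065091 to 112235938), a neuronal phosphoprotein gene, and Adgrl4, of endothelial cells, chosen after their values were seen, were lower, Arpp21 by -0.37 (adjusted p = 0.000153) and Adgrl4 by -0.33 (adjusted p = 0.0308). In all, edgeR called 33 of 21409 genes, 12 higher and 21 lower. In pool A alone (3 against 5 libraries) 44 were higher and 47 lower, 27 of them shared, and Hspa5 was at -0.62. DESeq2 called 87, and 15 were called with no pool term. Leaving out a library gave 4 to 49 genes (4 without WT 3, 17 without WT 5, and 8, 19, 15 and 7 without APP/PS1 1, 2, 3 and 5). Of 22 called genes named here, 4 (App, Prnp, Lamr1-ps1 and Arpp21) passed in all 10 of these fits, Hspa5 in 3, Dhcr24 in 2 and Acat2 in 1.

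At 4 months in brain, the list of clock genes was lower in APP/PS1, and no microglial list passed. In the circadian list 8 of 18 genes fell when adjusted over the list alone and none over all genes, with a median of -0.16 (adjusted p = 1.94e-07, and 0.0247 with an estimated correlation). Its members Tef (-0.21, adjusted p = 0.0573) and Per2 (-0.75, adjusted p = 0.0804) did not pass over all genes, and over the alternatives they ran from -0.28 to -0.08 and from -1.06 to -0.23. ER genes had a median of -0.29, with 15 of 20 lower over the list alone (adjusted p = 1.86e-15, and 0.158 with an estimated correlation), Herpud1 at -0.27 (adjusted p = 0.0872) and Manf at -0.43 (adjusted p = 0.129). Cholesterol genes had a median of 0.20, with 11 of 18 higher over the list alone (adjusted p = 3.4e-12, and 0.158 with an estimated correlation), Sqle at 0.28 (adjusted p = 0.119) and Ldlr at 0.63 (adjusted p = 0.144). In the earlier library series alone Sqle was at -0.04 and Ldlr at -0.08. The interferon (adjusted p = 0.000573, and 0.78 with an estimated correlation), oxidative phosphorylation (0.0143, and 0.832) and ribosome lists (0.0271, and 0.832) passed with the preset correlation only. Among single genes, Dio2, which activates thyroid hormone, fell by 0.62 (SE 0.12, adjusted p = 0.0130), from 95.6 ± 10.9 to 66.7 ± 8.49 CPM (n = 9 and 5). Dsp, a desmosome gene, changed by -0.67, Sowaha by -0.26, Ankrd13a by -0.22, Dusp7 by -0.21, and Rims4, of the presynaptic active zone, by -0.20. Arpp21 (-0.38, adjusted p = 2.9e-05) and Adgrl4 (-0.36) fell, and Zfp941 (0.31) and Elf1 (0.37) rose. App rose by 1.04 and Prnp by 1.55, Psen1 was at 0.11 (adjusted p = 0.20), Cst7 at 1.24 (adjusted p = 0.43), and Lamr1-ps1 at 6.79 ± 0.73 CPM against 0. The test called 14 genes, 5 higher and 9 lower (n = 5 and 9). Within pool A (1 against 7 libraries) 3 were higher and 1 lower, and within pool D (4 against 2) 5 and 23, and all 14 genes had the same sign in both. DESeq2 called 99 and the fit with no pool term 109. Leaving out a library gave 6 to 268 genes, with 268 without APP/PS1 1, 6 without APP/PS1 4 or WT 9, and 9 without APP/PS1 5 or WT 8. Of 13 called genes named here 6 passed in all 14 of these fits, Ankrd13a in 8, Dsp in 7 and Elf1 in 4, and over all alternatives Dsp was at -0.19 at its weakest and Ankrd13a at -0.10.

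At 5 months in brain, the lists of plaque-associated microglia and complement were higher in APP/PS1 than in WT, and the activity-dependent gene Arc was lower. Cst7, which encodes cystatin F and is expressed by microglia near plaques, rose by 1.99 (SE 0.32, adjusted p = 0.000168), from 0.121 ± 0.094 to 0.516 ± 0.237 CPM (SD, n = 13 and 11), a low level. Lyz2 (0.44, adjusted p = 0.0298) and Ctsz (0.19, adjusted p = 0.046), a lysosomal protease, rose too. In the plaque-associated microglia list 3 of 26 genes rose and 10 when adjusted over the list alone (median 0.14, adjusted p = 1.38e-13, and 0.00405 with an estimated correlation). C1qc (0.20, adjusted p = 0.0464) was the complement gene that passed, with 6 of 12 higher over the list alone (median 0.19, adjusted p = 1.18e-07, and 0.00536 with an estimated correlation). Reactive astrocyte genes had a median of 0.11, with none passing over all genes and 6 of 21 over the list alone (adjusted p = 9.59e-06, and 0.0335 with an estimated correlation). Of 14 immediate early genes, Arc, induced by neuronal activity, fell by 0.60 (adjusted p = 0.046), from 232 ± 45.9 to 159 ± 35.3 CPM, and 11 were lower over the list alone (median -0.40, adjusted p = 7.07e-12, and 0.11 with an estimated correlation). S100a8 (2.75, adjusted p = 0.0148) and S100a9 (2.49, adjusted p = 0.0144), neutrophil genes of the leukocyte list (adjusted p = 0.0104, and 0.223 with an estimated correlation), rose on average, at 1.43 ± 2.30 against 0.216 ± 0.134 CPM for S100a8. In CPM of total counts, S100a8 was at 7.75 in APP/PS1 7 and 3.24 in APP/PS1 3, and without those libraries 12 genes were called instead of 21. Over 11 alternative fits Cst7 passed in 11, S100a8 and S100a9 in 8, Ctsz in 7, C1qc in 6, and Arc and Lyz2 in 3. At its weakest in these fits S100a8 was at 1.43 and S100a9 at 1.20.

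The remaining lists at 5 months differed less. Passing with the preset correlation but not the estimated one were homeostatic microglia (3 of 12 higher over the list alone, adjusted p = 0.00034, and 0.144 with an estimated correlation), interferon (0.000218, and 0.412), myelin (median -0.06, 0.000718, and 0.404), oligodendrocyte precursors (3 lower over the list alone, 0.011, and 0.11), the clock (lower, 0.0248, and 0.404), ribosome (median 0.06, 2.81e-06, and 0.557), the mitochondrial genome (0.00034, and 0.356), oxidative phosphorylation (0.0104, and 0.656), meninges (0.0283, and 0.636) and rods (0.0281, and 0.636). The rod list, whose genes belong to the retina, had a median of 0.61 in brain. No call was made for antigen presentation (adjusted p = 0.626), astrocyte identity (0.822), glutamatergic (0.399), GABAergic (0.448) and striatal neurons (0.583), thalamus and cerebellum (0.435), endothelium (0.438), choroid plexus (0.658), blood (0.264), ER stress (0.622), cholesterol synthesis (0.127), amyloid processing (0.343), cones (0.575), bipolar (0.448), amacrine (0.435) and ganglion cells (0.156), Muller glia (0.507), pigment epithelium (0.438), lens (0.94) or cornea and muscle (0.346). Ccn3, a matrix protein gene, rose by 0.26 (adjusted p = 5.89e-05), Scrg1 by 0.24 and Snhg1 by 0.24, and Rnf122 changed by -0.26. App rose by 1.05, Prnp by 1.57 and Psen1 by 0.17 (adjusted p = 1.79e-05), Lamr1-ps1 was at 5.94 ± 0.49 against 0.00266 CPM, and Arpp21 fell by 0.28 (adjusted p = 1.95e-06). The test called 21 genes, 18 higher and 3 lower. Within pool A 3 were higher and 1 lower and Cst7 was at 1.42, within pool B 9 and 2 with Cst7 at 2.31, and all 21 genes kept their sign in each. DESeq2 called 56, the fit with no pool term 12, and that of these groups alone 7.

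At 6 months in brain, Cst7 was the microglial gene that passed, rising by 3.75 (SE 0.57, adjusted p = 5.25e-05) from 0.090 ± 0.058 to 1.13 ± 0.31 CPM (SD, n = 7 and 5). In the plaque-associated microglia list 3 of 26 genes were higher over the list alone and 24 had a positive change (median 0.15, adjusted p = 2.33e-12, and 0.00797 with an estimated correlation). Cholesterol genes had a median of 0.21, with 6 of 18 higher over the list alone (adjusted p = 7.26e-16, and 0.093 with an estimated correlation), reactive astrocyte genes 0.12 (0.00019, and 0.093) and ER genes -0.16 (1.02e-05, and 0.411). App rose by 0.98, Prnp by 1.48, Lamr1-ps1 was at 5.62 ± 0.85 against 0.00274 CPM, and Arpp21 fell by 0.34 (adjusted p = 0.0227), passing in 6 of 12 fits with a library left out. Psen1 was at 0.10 (adjusted p = 1.0). These 5 genes, 4 higher and 1 lower, were all that edgeR called, where 736 had an unadjusted p under 0.05 and DESeq2 called 18. Pool and genotype nearly coincided at this age: within pool B (1 against 7 libraries) 6 genes were higher and 2 lower, all 5 had the same sign, and Cst7 was at 3.62. Rod genes were lower in APP/PS1 (median -0.73, adjusted p = 0.0103, and 0.528 with an estimated correlation), and rhodopsin reads in brain differed by pool, at 0.559 ± 0.196, 16.7 ± 19.4 and 14.8 ± 6.87 CPM of total counts in A, B and D.

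Whether the genotype difference in brain grew from 2 to 6 months was tested as an interaction. Cst7 alone passed, its genotype difference being 4.21 larger at 6 months (SE 0.80, adjusted p = 0.0385), and 696 genes had an unadjusted p under 0.05. App (-0.03, adjusted p = 1.0), Prnp (-0.02) and Psen1 (0.02) showed no change of that difference. In the plaque-associated microglia list 5 genes passed over the list alone (median 0.16, adjusted p = 6.75e-07, and 0.245 with an estimated correlation). ER genes moved by a median of 0.23 (adjusted p = 1.78e-07, and 0.418 with an estimated correlation). DESeq2 called 17 genes. The count fell to 0 without any one of 16 of the 22 libraries. Cst7 lost the call in the earlier library series alone (4.36, adjusted p = 0.432) and in a fit of only the groups compared (4.38, adjusted p = 0.244).

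**Figure D2:**
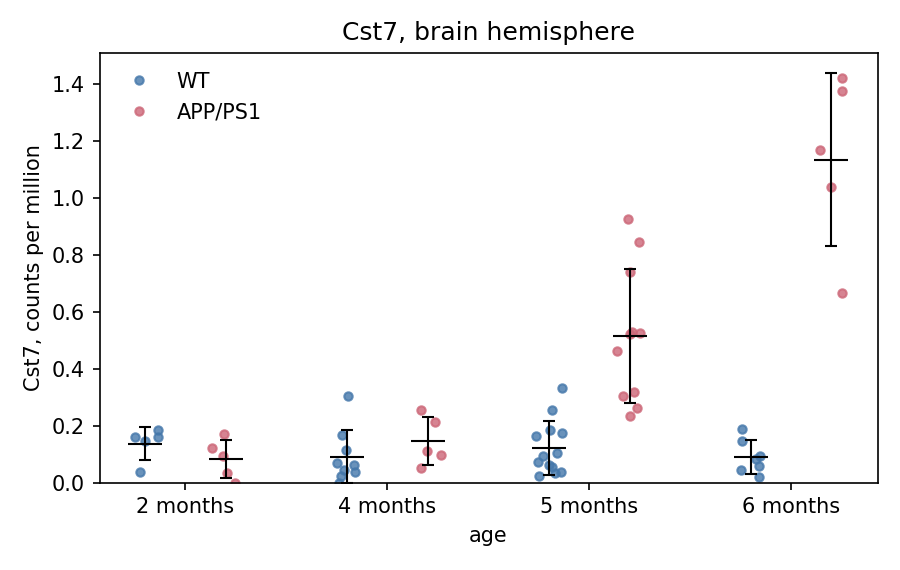
Cst7 in brain in CPM of total counts (linear axis from 0) by age. Each point is a library, blue for WT and red for APP/PS1, with the mean as a black dash and bars of 1 SD. The genotypes overlap at 2, 4 and 5 months and separate at 6 months.

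With age in WT brain, from 2 to 6 months, the lipid transporter gene Abca8a rose, and the proliferation marker Mki67 and the oligodendrocyte genes Tspan2 and Cldn11 fell. Abca8a rose by 0.65 (SE 0.09, adjusted p = 2.48e-06), from 14.4 ± 0.761 to 23.6 ± 1.42 CPM (SD, n = 5 and 7). Mki67 fell by 0.89 (adjusted p = 0.0378), from 3.28 ± 0.256 to 1.83 ± 0.291 CPM. Tspan2 was at -0.37 (adjusted p = 8.09e-06) and Cldn11 at -0.33 (adjusted p = 0.00174), with 5 of 13 myelin genes lower over the list alone. Tnnc1 (-0.82), Fst (-0.72), the matrix gene Tnc (-0.49), Nrep (-0.48), Car4 (-0.35), the thalamic kinase gene Prkcd (-0.26) and the pericyte gene Rgs5 (-0.21) fell as well. Mmp11 (0.81), Lca5l (0.65), Ntn5 (0.64), Fam131c (0.63), the complement gene C4b (0.54, adjusted p = 0.0481) and Csf1 (0.26, adjusted p = 0.0472) rose. None of the 13 lists that passed with the preset correlation held with an estimated one. They included antigen presentation (median 0.27, 8.35e-05, and adjusted p = 0.313 with an estimated correlation), thalamus and cerebellum (-0.18, 1.06e-05, and 0.313), ER genes (-0.29, 14 of 20 lower over the list alone, 1.97e-11, and 0.313) and rods (1.07, 0.000699, and 0.425). Hsp90b1 (-0.31, adjusted p = 0.093), Manf (-0.47, adjusted p = 0.11) and the rod gene Cngb1 (1.30, adjusted p = 0.12) did not pass. The test called 83 genes, 44 higher and 39 lower. At 2 months all WT libraries were of pool A and at 6 months all of pool B, so no within-pool value exists, and 2233 genes were called with no pool term and 11 without the 5 libraries richest in rhodopsin reads. Leaving out a library gave 18 to 158 genes (18, 35, 43 and 50 without WT 5, 4, 3 and 1 at 2 months, and 24, 46, 54 and 158 without WT 7, 6, 1 and 4 at 6 months). Of 17 called genes named here 4 (Abca8a, Tspan2, Tnnc1 and Cldn11) passed in all 12 of these fits, Mki67 in 5 and C4b in 2.

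With age in APP/PS1 brain, genes of plaque-associated microglia, complement and antigen presentation rose. Cst7 rose by 4.30 (SE 0.57, adjusted p = 1.66e-06), from 0.084 ± 0.068 to 1.13 ± 0.31 CPM (SD, n = 5 and 5), Itgax by 1.85 (adjusted p = 0.0177), Gpnmb by 0.53 (adjusted p = 0.0378), Trem2, a microglial receptor, by 0.46 (adjusted p = 0.026), its adaptor Tyrobp by 0.43 (adjusted p = 0.0216) and Mpeg1 by 0.32 (adjusted p = 0.0136). In that list 7 of 26 genes rose and 15 over the list alone (median 0.32, adjusted p = 5.12e-21, and 0.000263 with an estimated correlation). C4b rose by 0.75 (adjusted p = 0.000789), from 29.8 ± 2.52 to 48.8 ± 5.05 CPM, with 4 of 12 complement genes higher over the list alone (6.83e-08, and adjusted p = 0.00599 with an estimated correlation). Psmb8, of the immunoproteasome, rose by 0.88 (adjusted p = 0.0202), and 10 of 13 antigen presentation genes over the list alone (median 0.44, 2.35e-11, and adjusted p = 0.00631 with an estimated correlation), H2-K1 being at 0.34 (adjusted p = 0.0676). Endothelial and mural genes were lower (median -0.14, 8.1e-07, and adjusted p = 0.0268 with an estimated correlation), Acta2 at -0.33 (adjusted p = 0.19) and Myh11 at -0.34 (adjusted p = 0.23). Striatal (median -0.12, 1.89e-07, and adjusted p = 0.0804 with an estimated correlation), glutamatergic (-0.07, 2.99e-06, and 0.15) and interferon lists (0.29, 3.1e-06, and 0.258) passed with the preset correlation only. Abca8a rose by 0.84 (adjusted p = 3.04e-11), Mfsd7a by 1.04, Fbxw15 by 1.02 and Ngfr by 0.44. Mybpc3 (-0.74), Tnnc1 (-0.72), Tnc (-0.47), Car4 (-0.32), Rgs4 (-0.29), a regulator of G protein signalling, Camk4 (-0.29), a neuronal kinase, and Cldn11 (-0.27) fell. App (-0.03) and Prnp (0.01) did not pass. The test called 43 genes, 30 higher and 13 lower, and with only these groups in the fit 1. Within pool D (4 against 2 libraries) 3 were higher and 1 lower, all 4 shared, and all 43 genes had the same sign. Leaving out a library gave 12 to 147 genes (12, 17 and 27 without APP/PS1 4, 3 and 5 at 2 months, and 147, 14, 23, 23 and 19 without APP/PS1 2, 1, 3, 4 and 5 at 6 months). Of 19 called genes named here 4 (Cst7, C4b, Abca8a and Rgs4) passed in all 10 of these fits, Trem2 in 4, Tyrobp in 3 and Gpnmb in 2.

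In retina at 2 months, transcripts of skeletal muscle, connective tissue and myelin, which are scarce in retina, were far higher in APP/PS1 than in WT. Acta1, skeletal muscle actin, was at 2111 ± 3947 CPM against 2.24 ± 1.17 (SD, n = 5 and 5), a fitted rise of 10.20 (SE 1.37, adjusted p = 8.94e-05). The muscle genes Myh13 (11.93), Ckm (10.11), Des (8.96) and Mylpf (8.67), the collagen gene Col1a1 (6.86), Bgn (5.29), the myelin gene Mal (5.74) and Cd74 (6.50) rose. The excess differed between libraries: in CPM of total counts Acta1 was at 6210, 885, 436, 76.4 and 1.87 in APP/PS1 1 to 5, against 1.45 to 4.32 in WT. Rhodopsin was at 3111 CPM of total counts in APP/PS1 1 and 23812 to 31836 in APP/PS1 2 to 5, beside 28455 to 30196 in WT. The list of cornea, iris, ciliary body and muscle had 12 of 15 genes higher (median 8.67), myelin 12 of 12, plaque-associated microglia 22 of 23, complement 11 of 12, interferon 19 of 20, antigen presentation 12 of 13, pigment epithelium 14 of 16 and lens 7 of 15, and 4 of 13 cone and 3 of 17 rod genes were lower. Only the transgene list held with an estimated correlation (adjusted p = 0.0172), of 26 that passed with the preset one, plaque-associated microglia being at 0.242. App rose by 2.35 (adjusted p = 8.28e-11), Prnp by 1.55 and Psen1 by 0.43 (adjusted p = 0.00143), and without APP/PS1 1 to 3 Psen1 was at 0.13 (adjusted p = 0.564). In all 7637 genes were called, 5514 higher and 2123 lower, and 18 (6 higher, 12 lower) without APP/PS1 1 to 3, a choice made after seeing the data. In that fit the genotypes of this age lay in different pools, and Tspan7 was called at -1.64 although it stood at 455 ± 31.4 and 453 ± 26.9 CPM (n = 2 and 5). Within pool C, which holds APP/PS1 1 to 3, 6217 were higher and 1672 lower.

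**Figure D3:**
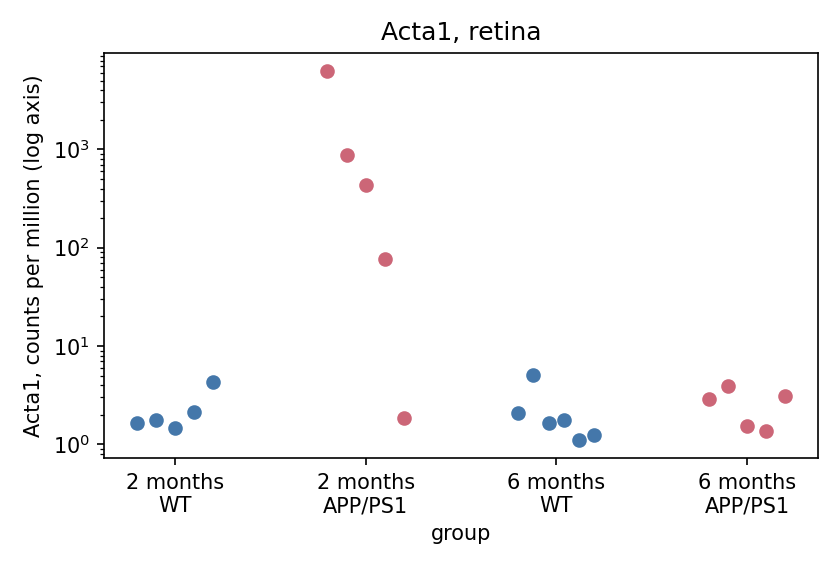
Acta1 in retina in CPM of total counts, on a log axis. Each point is a library, blue for WT and red for APP/PS1, in replicate order within a group; 4 of the 5 APP/PS1 libraries of 2 months lie above the WT libraries, from 76.4 to 6210 CPM.

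In retina at 6 months 5 genes were called, App, Prnp and Lamr1-ps1 among them. App rose by 2.54 (SE 0.11, adjusted p = 1.42e-10) and Prnp by 1.86, Lamr1-ps1 was at 3.16 ± 0.51 against 0.00362 CPM, and Psen1 was at 0.40 (adjusted p = 0.43). Abhd2, a lipid hydrolase gene, rose by 0.95 (SE 0.14, adjusted p = 0.00871; 52.7 ± 16.01 against 40.8 ± 2.65 CPM, SD, n = 5 and 6) and Thbs1, a matrix glycoprotein gene, by 2.36 (adjusted p = 0.0387; 7.16 ± 5.22 against 3.84 ± 1.15). Against these 5 genes, 2220 had an unadjusted p under 0.05 and 583 were called by DESeq2, 3 with no pool term, and 8 without the 2-month APP/PS1 libraries 1 to 3, which enter through the shared pool term. Within pool C (1 against 6 libraries) 3 were higher and 1 lower. Of 24 lists that passed with the preset correlation, such as lens (median 4.82, adjusted p = 1.03e-07, and 0.354 with an estimated correlation) and pigment epithelium (1.87, 7.37e-13, and 0.156), only the transgene list held (3.33e-05). The 2-month APP/PS1 libraries 1 to 3 enter these medians too through the pool term. In CPM of total counts the lens gene Crygs was at 15.5 ± 29.8 in APP/PS1 against 3.72 ± 8.45 in WT. The pigment epithelium gene Rpe65 was at 21.2 ± 24.7 against 7.15 ± 3.65. Leaving out APP/PS1 1, the pool C library of this group, raised the count to 1984, and the lowest count was 4. Without that library the genotypes of this age lay in different pools. The pool term then came from the 2-month APP/PS1 libraries alone, so the 1984 calls cannot be read as a genotype difference. With each library left out in turn, Abhd2 passed in all 11 fits and Thbs1 in 2, and each passed in 5 of the 11 other fits. The fits with a library left out include that without APP/PS1 1, which cannot be read as a genotype difference. Both lost the call without the 2-month APP/PS1 libraries 1 to 3, at 0.97 for Abhd2 (adjusted p = 0.0872) and 2.09 for Thbs1 (adjusted p = 0.179). In that fit APP/PS1 1 of 6 months was the only APP/PS1 library in the pool of the WT libraries, so both values rest on it. With no pool term both lost the call as well, at 0.37 and 0.90, so the larger fitted rises depend on the pool term. Whether the genotype difference in retina changed between 2 and 6 months gave 0 genes by edgeR, 1128 with an unadjusted p under 0.05 and 255 by DESeq2. The smallest p were those of Nox4 (-3.13), Pof1b (-5.19) and Dsg3 (-10.37), none passing (adjusted p = 0.351), App was at 0.19 and Prnp at 0.31 (adjusted p = 0.855), and none of 22 lists held with an estimated correlation. The count became 16 without APP/PS1 1 and 244 without APP/PS1 5 of 2 months.

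With age in WT retina, Bcl2, an inhibitor of cell death, rose by 0.68 (SE 0.07, adjusted p = 8.7e-05), from 21.5 ± 1.32 to 34.4 ± 2.52 CPM (SD, n = 5 and 6). Col4a3, a basement membrane collagen gene, rose by 1.11 (adjusted p = 0.0115; 30.9 ± 4.99 to 66.7 ± 10.9 CPM), Parp4 by 0.55 (adjusted p = 0.0130) and Tm7sf3 by 0.38 (adjusted p = 0.0394). With each library left out in turn, Bcl2 passed in all 11 fits, Col4a3 and Parp4 in 8 and Tm7sf3 in 0. ER genes had a median of -0.31, with none passing over all genes and 10 of 20 lower over the list alone (adjusted p = 6.81e-18, and 0.61 with an estimated correlation). The test called 5 genes, all higher, with 1 without WT 1, 3 or 4 of 2 months, 73 by DESeq2, and 623 (350 higher, 273 lower) without the 2-month APP/PS1 libraries 1 to 3, which share the fit. All these libraries were of pool C, which fitted alone gave 1 gene, the 5 having the same sign. With age in APP/PS1 retina Bcl2 (0.59, adjusted p = 0.00552), Col4a3 (1.09) and Dqx1 (0.59) rose. Muscle genes fell, such as Trdn (-10.70) and Mylk2 (-11.36), and so did Pi16 (-7.24), Cyp2a5 (-8.60) and the cell cycle gene Top2a (-6.97), their 2-month SD exceeding the mean of 15.5 to 196 CPM. Without the 2-month APP/PS1 libraries 1 to 4 Mylk2 was at 0.00, Pi16 at 0.41 and Cyp2a5 at 0.54. At their weakest over the alternatives Trdn was at -0.97 and Top2a at -0.04. The test called 18 genes, 7 higher and 11 lower, against 159 without the 2-month APP/PS1 libraries 1 to 3, 14 without 1 to 4, 770 by DESeq2 and 3658 with no pool term. Within pool C (1 against 3 libraries) none was called, and within pool D (4 against 2) 7 were higher and none lower, 1 of them shared. Leaving out a library gave 1 to 1434 genes (1434, 70, 110, 1 and 653 without APP/PS1 1 to 5 of 2 months and 2, 50, 1, 2 and 1 without APP/PS1 1 to 5 of 6 months), and of 8 called genes named here 0 passed in all 10 of these fits, Bcl2 passing in 8. None of 22 lists held with an estimated correlation, the cornea and muscle list being at 0.225.

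Whether the genotype difference was larger in retina than in brain was tested in the 20 animals with both tissues, with the animal as a block. The log2 ratio of App was larger in retina, by 1.16 at 2 months (SE 0.15, adjusted p = 0.000365) and by 1.44 at 6 months (SE 0.18, adjusted p = 0.00588). Its level in CPM of total counts was lower there: at 2 months 1462 in APP/PS1 and 311 in WT, against 3506 and 1749 in brain. At 6 months these were 1775 and 324, against 3417 and 1718. Prnp did not pass at either age (-0.16, adjusted p = 0.44, and 0.32, adjusted p = 0.62), and at 2 months it ran from -0.19 to 0.44 over the alternatives. At 6 months it ran from 0.12 to 0.65, passing in 1 of the 6 fits other than those with an animal left out. The 2-month value includes retina APP/PS1 1 to 3, without which retina Prnp stood at 1376 ± 40.7 against 383 ± 12.5 CPM (SD, n = 2 and 5). A larger ratio of Prnp in retina is thus not excluded. At 6 months App was the 1 gene called, Psen1 being at 0.21 (adjusted p = 0.62), against 1529 with an unadjusted p under 0.05 and 41 by DESeq2, and the count was 42 without the animal of APP/PS1 1 and 2 without that of WT 3. At 2 months 7967 genes were called, 3419 higher and 4548 lower, where the median of all genes was -0.19. They included Acta1 (8.22), Cfh (1.76), Csf1r (1.53) and Gngt2 (-1.27), a cone gene. Without the animals of APP/PS1 1 to 3, 1 gene was called, and 3923 to 4241 without that of WT 1, 3 or 5. No list but that of the transgenes at 6 months (adjusted p = 0.012) held with an estimated correlation. In CPM of total counts, Hspa5 in the brains of the 2-month animals ran from 439 to 603 in WT and from 226 to 333 in APP/PS1, and in their retinas from 391 to 590 and from 209 to 314.

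**Figure D4:**
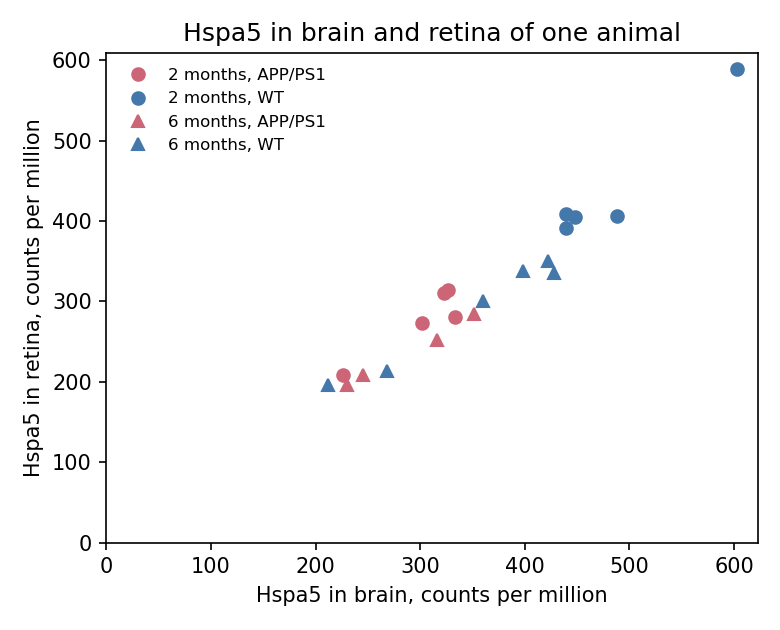
Hspa5 in CPM of total counts in the brain (horizontal axis) and the retina (vertical axis) of the 20 animals with both libraries, both linear from 0. Each point is an animal, circles for 2 and triangles for 6 months, blue for WT and red for APP/PS1; animals high in brain were high in retina, and the 2-month WT animals lie at 439 CPM or more in brain.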

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

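Chosen only after the result was seen were the tests of the retinas at 2 months, the test of the library pool for the ER chaperones, the comparison with random lists, the counts over other splits without the genes that tag the genotype and the fits without particular libraries. The counts over other splits of all genes and the test of a state of the whole animal were set before.

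The 7637 calls in retina at 2 months came with muscle, connective tissue, myelin and lens transcripts that differed widely between the 5 APP/PS1 libraries. Over the 5514 genes called higher the median log2 excess was 1.78, 0.644 and 0.737 in APP/PS1 1 to 3, and 0.2302 and 0.155 in APP/PS1 4 and 5. Of these genes, 998 and 154 lay over 2 fold in APP/PS1 4 and 5. The genes were picked by the same contrast, in which APP/PS1 1 to 3 share the pool of the WT libraries. The medians therefore cannot decide on a smaller genotype effect present in every APP/PS1 retina. The later library pool is argued against, since 7889 genes were called among libraries of the earlier pool alone. Tissue from outside the retina in APP/PS1 1 to 3 is a candidate explanation, as, in CPM of total counts, Mbp reached 3063 and Krt12 454 in APP/PS1 3, Crygs 581 in APP/PS1 1 and rhodopsin fell to 3111 in APP/PS1 1. An effect of the genotype on part of these genes stays open, since without those 3 libraries the genotypes of this age lay in different pools, joined by 1 library of 6 months, and the 18 calls of that fit included Tspan7 at -1.64 with 455 against 453 CPM.

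In brain at 2 months the ER chaperones were lower in APP/PS1, and the mean of their list in an animal's brain went with that in its retina once group means were removed. Pearson's r was 0.9472 over 20 animals (Spearman 0.964, permutation p = 1e-05 for both, the smallest that resampling can give, adjusted p = 2e-05 over 2 lists, and 0.931 without the 2 animals farthest from the median), with r from 0.935 to 0.999 within the 4 groups of 4 to 6 animals. None of 10000 random lists of that size reached it (median -0.026, highest 0.784). The genes of a random list need not vary together, so this sets the list apart from unrelated genes only. The library pool as the cause is argued against, since Hspa5 was at -0.6201 in the first pool alone. Mean Hspa5 was highest in 2-month WT in both tissues, at 440 CPM of total counts in retina. The other retina groups stood at 277 (APP/PS1 at 2 months), 236 (APP/PS1 at 6 months) and 289 (WT at 6 months). The same 2-month WT libraries enter the lower ER lists with age in WT brain and WT retina. A state of the whole animal at collection, such as its feeding, temperature or handling, is a candidate explanation of the spread between animals, and whether it also differed between genotypes, or the genotype itself lowered these genes, was not tested.

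Other single values stood apart from their group. Among 100 groups and measures tested, 13 held such a library, where chance gives about 1 in 20. The total of brain 6-month APP/PS1 5 was 91.65 M reads, against 49.5 to 52.4 in the others, with 28660 genes detected. In retina at 2 months, APP/PS1 1 had 22890 genes detected, 12.01% mitochondrial counts and Arpp21 at 40.31 CPM, against 5.23 to 13.3, and WT 3 had 24580 genes detected and Hspa5 at 589.5 CPM, against 391 to 408. Reads in no feature equalled 19.73% of gene counts in brain 2-month WT 3 and 18.26% in brain 4-month APP/PS1 1. Psen1 was at 70.23 CPM in brain 4-month APP/PS1 1 and 66.04 in 4-month WT 3, Prnp at 669.2 in brain 6-month WT 6, and Cst7 at 0.03574 in brain 2-month WT 5, all in CPM of total counts. A genotype difference that changed between 2 and 6 months was called for 1 gene in brain. One that differed between tissues was called for 7967 genes at 2 months and 1 at 6 months.

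Counts were repeated over 100 splits of the same libraries, the real one included. The share of splits that called as many genes was under 0.05 for brain at 2 months (33 genes, highest other split 4, 1 split as large), 4 months (14, 4, 1), 5 months (21, 136, 2) and 6 months (5, 867, 2), for age in WT brain (83, 26, 1) and APP/PS1 brain (43, 163, 3), and for retina at 2 months (7637, 3260, 1), 6 months (5, 0, 1) and age in WT retina (5, 0, 1). It was not under 0.05 for the brain interaction (1 gene, highest other 43, 8 splits as large), the retina interaction (0, 1687, 100) or age in APP/PS1 retina (18, 6649, 10). Between tissues 60 splits were drawn, and the share was under 0.05 at 2 months (7967, 723, 1) but not at 6 months (1 gene, highest other 1, 3 splits as large). App, Prnp, Psen1 and Lamr1-ps1 tag the genotype, so that the real labels had to call some of them, and App was the 1 gene called between tissues at 6 months. Counted without these 4 genes, the share stayed under 0.05 for brain at 2 months (30 genes, highest other split 2, 1 split as large), 4 months (11, 2, 1), 5 months (17, 136, 2) and 6 months (2, 867, 2), for retina at 2 months (7633, 3257, 1) and 6 months (2, 0, 1), and between tissues at 2 months (7966, 723, 1). Splits that called many times the real count, as with 867 against 5 and 6649 against 18, point to a structure of the samples other than the groups, and the pools were not kept together in these splits. In brain and retina at 6 months the real genotypes nearly coincide with the pools, so the splits cannot tell the 2 apart there. Genotypes and pools also overlap in part at 2 months and in brain at 4 months. The shares were not adjusted over the comparisons.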

How the results depend on the processing

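The fits without particular libraries, other than those leaving out each library in turn, were chosen after the data were seen, and all other alternatives before. The cause of a changed count was not tested. Where a fit left 1 library in an arm, that library was assumed to vary like the other groups. Counts are of genes called, and in brain the order is 2, 4, 5 and 6 months, the interaction, age in WT and age in APP/PS1.

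Size factors in place of TMM left every count within 1.5 times and moved no share of higher calls by over 10 points. The largest shift was between tissues at 2 months, from 42.9% to 48.0% higher, where the median of all genes moved from -0.19 to -0.11. Of 504 list medians 3 changed sign, 0 of them in lists that passed. DESeq2 called 87, 99, 56, 18, 17, 224 and 87 genes in brain, 583, 255, 73 and 770 in retina at 6 months, for the interaction and for age in WT and APP/PS1, and 41 between tissues at 6 months. These sets held all the genes of the main test in each of these comparisons except 20 of 21 at 5 months and 81 of 83 for age in WT brain. Without the filter on low counts, 39 were called for age in WT brain, 135 for age in APP/PS1 retina and 3964 between tissues at 2 months.

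With no pool term the counts were 15, 109, 12 and 15 in brain by age and 2233 for age in WT, and in retina 5006 at 2 months, 3 at 6 months, 822 for the interaction and 3658 for age in APP/PS1. With 2 library series in place of 3 pools they were 12 at 5 months and 2454 for age in WT brain. The earlier series alone gave 4 at 4 months, 8 at 6 months, 2 for the interaction and 8 for age in APP/PS1 in brain, and 1 and 0 for age in WT and APP/PS1 retina. Fits of only the groups compared gave 65, 134 and 7 at 2, 4 and 5 months in brain, 2 for the interaction, and 2775 and 1 for age in WT and APP/PS1, and in retina 3588, 31, 735 and 0 at 2 and 6 months and for age in WT and APP/PS1. Cst7 was not among the 2 interaction genes of the earlier series or of the groups alone. With the eye letter as a further term 3606 were called in retina at 2 months and 47 for age in APP/PS1. Without the tissue by series term 2821 were called between tissues at 2 months.

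The replicate numbers of the labels did not pair the libraries, since the correlations of same-numbered libraries ran from -0.255 to 0.356. With the replicate block the counts were 17, 13, 8, 5, 0, 17 and 29 in brain, and 3229, 3, 0, 3 and 2 in retina at 2 and 6 months, for the interaction and for age in WT and APP/PS1. For the brain interaction Cst7 was at 3.91 in that fit. Between tissues, where the animal was the block of the main fit, 8325 and 2 genes were called without it at 2 and 6 months.

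Without brain 5-month APP/PS1 2, which stood apart on the first components, 65, 38, 215 and 72 genes were called at 2 and 4 months and for age in WT and APP/PS1. Without the 5 brain libraries richest in rhodopsin 11 were called for age in WT, and without the 2 richest in S100a8 12 at 5 months. Without retina 2-month APP/PS1 1 to 3, 18, 8, 623 and 159 were called in retina at 2 and 6 months and for age in WT and APP/PS1. These were 1969, 979, 337 and 253 when the pool term was dropped as well. Without APP/PS1 1 to 4, the counts were 38 and 11 at 2 and 6 months, 1 for the interaction, and 683 and 14 for age in WT and APP/PS1. Without the animals of libraries 1 to 3, 1 and 6 genes were called between tissues.

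Leaving out each library in turn gave 4 to 49 genes at 2 months, 6 to 268 at 4 months and 4 to 5 at 6 months in brain, 0 to 1 for the interaction, 18 to 158 for age in WT and 12 to 147 for age in APP/PS1. In retina the ranges were 6510 to 9100, 4 to 1984, 0 to 244, 1 to 5 and 1 to 1434 in the order of the block, and between tissues 3923 to 8978 and 1 to 42. The 5-month groups, of 13 and 11 libraries, were not tested in this way. App kept its call in each of these fits of the genotype comparisons. Cst7 kept its call in all 12 of these fits at 6 months but in 6 of 22 for the interaction, C4b in 2 of 12 with age in WT brain and 10 of 10 in APP/PS1, and Tyrobp, Trem2 and Gpnmb in 3, 4 and 2 of 10.

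Of the values of named genes under all alternatives, 611 lost the call and 46 gained it, and 9 values of genes that had passed turned or went to 0, all without retina 2-month APP/PS1 1 to 4. In retina at 2 months the values became -0.14 for Acta1, -0.90 for Ckm, -0.68 for Myh13, -1.24 for Mylpf, -0.32 for Col1a1 and -0.42 for Mal, and with age in APP/PS1 0.41 for Pi16, 0.00 for Mylk2 and 0.54 for Cyp2a5. Genes that had not passed changed sign too, with Sqle at -0.04 and Ldlr at -0.08 in brain at 4 months in the earlier series, Prnp between tissues at 2 months at up to 0.44, and App, Prnp or Psen1 in the brain interaction and Prnp with age in APP/PS1 brain. Of the tests of 36 lists in 14 comparisons 224 passed with the preset correlation and 18 with an estimated one, 200 with no pool term and 208 in the earlier series. All 18 tests of App, Prnp and Psen1 passed with size factors and with any 1 library left out of the groups other than those of 5 months.

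Mean totals were 52.2 M reads in brain and 50.5 M in retina, and the biological coefficient of variation 0.0852 and 0.313. In retina at 6 months 13.6% of simulated changes of 2 fold were recovered among 19934 genes, and in brain at 6 months 93.9% among 21409. The retina simulation took the spread of the fit with 2-month APP/PS1 1 to 3, so differences of that size were mostly not detectable in that fit. A fit without those libraries was not simulated. There smaller changes were called with age in WT retina, such as Rps18 at -0.22.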

Other observations

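The fits of the retinas without 2-month APP/PS1 libraries 1 to 3, their gene names, the genes of the Tspan7 pattern and its tests, the comparison with random lists and the rod transcripts were chosen only after the result was seen. The test of the clock between tissues was set before. For the region around Arpp21 the rule of the test was set before its result. That gene and the mean over ages used there were chosen after the data were seen.

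Without those 3 libraries, ageing in WT retina from 2 to 6 months came out in more genes. There 350 genes rose and 273 fell of 20744 tested (n = 6 and 5). Glb1l3, a beta-galactosidase-like gene, rose by 1.18 (adjusted p = 5.1e-10), from 26.7 ± 1.79 to 60.7 ± 3.50 CPM, Csrp3 by 1.67, Gsc2 by 1.35, Rimbp3 by 1.17 and Col4a3 by 1.11. The histocompatibility gene H2-K1 (0.38) and Stat1 (0.27), of interferon signalling, rose, while Tmem26 (-1.47), Gfap, an intermediate filament of reactive Muller glia (-0.77, adjusted p = 0.0248), and Car14 (-0.42) fell. Of 20 heat shock and ER genes 6 fell, Creld2 (-0.46) among them, and 16 over the list alone (adjusted p = 2.8e-11, and 0.95 with an estimated correlation). Of 27 ribosomal genes 5 fell, such as Rps18 (-0.22), and 9 over the list alone (adjusted p = 1.1e-08, and 0.95 with an estimated correlation). In APP/PS1 retina 48 rose and 111 fell (n = 5 and 2), with Glb1l3 at 1.33 (adjusted p = 1.59e-07). One of these 2 libraries, APP/PS1 4, held Acta1 at 76.4 CPM of total counts, fallen genes such as Pi16 stood at 22.6 ± 31.5 CPM at 2 months, and without that library as well 12 rose and 2 fell.

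The same fits called 18 genes between genotypes at 2 months and 8 at 6 months, among them Tspan7 (-1.64 and -1.63) and Mid1ip1 (-1.57 and -1.70), neighbours on chromosome X (10485158 to 10596605, and 10715013 to 10719690, GRCm38). Both calls rest on 1 animal of 6 months, APP/PS1 1 in retina, the group's only library of the earlier pool, and at 2 months Tspan7 was at 455 ± 31.4 against 453 ± 26.9 CPM. In CPM of total counts Tspan7 was at 243 in its brain and 152 in its retina, against 702 to 989 in 59 other brains and 434 to 492.5 in 17 other retinas. A fault of a single library is argued against by the share of 0.3059 of the other brains' median in a second tissue, X dosage by a median ratio of 1.014 over 401 expressed X genes, and the genotype by a lowest share of 0.8795 of the WT mean in 31 other APP/PS1 libraries. The 31 libraries and 17 retinas leave out the retina 2-month APP/PS1 libraries 1 to 3 with muscle transcripts, among which Tspan7 fell to 223 CPM of total counts in APP/PS1 1 and was at 383 in APP/PS1 3. A local change of the genome in this animal may be the source, since 0 other genes of 10849 lay under 0.5 of the other libraries in both tissues, and the sequence itself was not read.

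A state of the whole animal was also tested with 9 output genes of the clock. The full list was lower in APP/PS1 brain at 4 months (adjusted p = 0.0247 with an estimated correlation) and did not pass that test at 2 months (adjusted p = 0.0945). The list means in brain and retina of 20 animals, with group means removed, had r = 0.4765 (permutation p = 0.067, Spearman 0.441, p = 0.053, the adjusted p being the same over 2 lists, and r = 0.532 without the 2 animals farthest from the median). Within groups r ran from -0.279 to 0.847, and 366 of 10000 random lists were as high, so a shared state of the clock in these animals stays open. All 20 animals were 2 or 6 months old, as no retina of 4 months was sequenced. The test therefore cannot decide whether such a state, for example the hour of collection, accounts for the difference at 4 months.

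Arpp21 was called as lower in APP/PS1 brain at all 4 ages, at 6 months in 6 of 12 fits with a library left out. The hypothesis that the region around it differs, for example through flanking sequence of another strain, was tested on p-values over the mean of the 4 ages. That mean was added after the data were seen. Of 330 genes within 10 Mb of Arpp21, 57 (17.3%) had p under 0.05, against 2548 of 21078 elsewhere (12.1%; one-sided Fisher's exact p = 0.003946). Genes in a region are not independent, and no sequence variant was read, so this may also reflect neighbours that share regulation.

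Rod transcripts were counted in brain libraries, with Rho from 0.272 to 0.902 CPM of total counts in pool A, 4.30 to 70.1 in pool B and up to 36.2 in pool D, and Sag at 1.47, 3.76 and 3.78 on average.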
